A study of Mus musculus with 18 samples.

How the data were processed

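RNA sequencing was measured in 18 mouse libraries. PTCP53 304 cells, a Sonic hedgehog (SHH) medulloblastoma line with the genotype Ptch1+/-; Trp53-/-, were exposed to vehicle or to CT-179, an inhibitor of the transcription factor OLIG2, for 24 h (culture day 1) or 144 h (culture day 6). Each of these 4 groups had 3 libraries. Whole brains came from Ptch1+/- mice dosed with vehicle or CT-179 over 12 days, from postnatal day 3 to postnatal day 15, with 3 libraries per group. The genotype label of the brains also carries the letters IR, which the labels leave unexplained. Nothing in the labels says whether replicates were separate cultures or animals, so p-values measure only the spread between these samples, which may be technical.

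Per the labels' protocols, RNA was purified on RNeasy columns, libraries were made with a SMARTer mRNA kit, and paired-end reads of 100 bases were sequenced. Per the submitters' processing notes, Trim Galore 0.5.0, STAR 2.6.0c, HTSeq 0.6.1p2, edgeR 3.28.1 and R 3.6 were used with the mm10 genome. The settings, the gene annotation and the strand of counting were not given in the sources used here. The authors deposited FPKM values per gene and library (fragments per kilobase of gene, scaled by the depth of the library), for 55183 genes in the cells and 19464 genes in the brains. For the brains the authors also deposited a log2 fold change, a mean log2 abundance, a likelihood ratio score, and a p-value with its false discovery rate per gene, per the file headers. That log2 fold change matched the mean of vehicle replicates 1 and 3 over the mean of CT-179 replicates 1, 2 and 3 across genes (Pearson's r 0.99999), and the grouping of all 6 libraries matched less closely (r 0.73508). The authors' comparison therefore left out vehicle replicate 2.

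The treatment of a brain library was taken from its treatment label. The titles of the brain libraries labelled CT-179 also contain the word vehicle. In the sample descriptions the libraries labelled vehicle carry the letter C and those labelled CT-179 the letter V. Every direction in the brain depends on the treatment label, and would turn around if the labels were crossed.

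Low FPKM values were multiplied by the exonic length of the gene in the GENCODE mouse annotation, which held 98.1% of the gene identifiers of the cell table and 97.0% of those of the brain table. Within a tolerance of 0.1 read and up to 20 reads, 90.0% to 92.0% of the low values of a cell library and 93.6% to 98.5% of those of a brain library were whole multiples of the value of 1 read. The reads implied in this way exceeded the scale of the FPKM values by a factor of 1.251 to 1.293 in cells and 1.179 to 1.343 in brain, for a reason that is not known. The values were therefore not treated as counts, and no count model was run. The implied depth was 2.86e+07 to 6.87e+07 reads per cell library and 1.70e+07 to 6.09e+07 per brain library. Replicates of 1 group differed by more than sampling noise in every pair, with a median chi-square of 2.12 or more times the Poisson value in cells and 6.06 or more in brain, so no library appeared to be deposited more than once.

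Genes with at least 1 FPKM in at least 3 libraries of a fit were tested on log2(FPKM + 1) with limma 3.58.1 in R 4.3.3 (group means, moderated variance with a mean trend, two-sided). P-values were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05 and no fold minimum. Fold changes are on the log2(FPKM + 1) scale, which understates the change of genes with low values. The 12 cell libraries shared 1 fit of 12510 genes, and the 6 brain libraries another of 13422 genes. The contrasts were CT-179 over vehicle at 24 h, at 144 h and in brain, the difference between the effects at 144 h and 24 h, and 144 h over 24 h in vehicle. Olig2 was also compared by an exact two-sided permutation test, whose smallest possible p with 3 libraries against 3 is 0.1.

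A set of 37 gene lists (pathways, cell types and tissues) was tested with camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists that had at least 5 tested members. These numbered 28 in cells and 35 in brain. Camera with an estimated correlation and fry were run beside it. Genes sharing a symbol count separately in a list. The comparisons, lists and rule for named genes were set before the data were examined. That plan held list tests for CT-179 at 24 h, at 144 h and in brain. It held none for the difference between times or for time in vehicle. The rule took Olig2, Olig1, Sox10, Gli1, Mki67 and Cdkn1a always where tested, the 8 largest rises and 8 largest falls among genes past the threshold whose CT-179 and vehicle libraries did not overlap and whose mean reached 1 FPKM in a group, leaving out unnamed gene models (Gm, Rik, accession-like and -ps names), and up to 4 members with the smallest p from each list that passed or had 2 or more members past the threshold. Where no gene passed, the 5 smallest p-values in each direction were taken, of which 1 in brain is not reported here. For 144 h over 24 h in vehicle the rule took the 5 smallest p-values in each direction.

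The test was checked on simulated data in which 100 genes were changed by 1.5-fold and 100 by 2-fold. With all cell libraries, 40 and 63 of them were recovered at 24 h (12409 genes), and 54 and 79 at 144 h (12430 genes). Without CT-179 144 h replicate 2 these numbers were 93 and 93 at 24 h, and 88 and 98 at 144 h (12384 genes). In brain 57 and 85 were recovered (13275 genes). Every simulated library had the same spread for a gene and independent noise, while much of the real spread in cells came from CT-179 144 h replicate 2. The recoveries with all cell libraries therefore need not hold for the real fit. Brain replicates also differed unevenly, with a median chi-square of 6.06 to 26.57 times the Poisson value between pairs. The recoveries in brain need not hold either.

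The alternatives set in advance were another pseudocount (0.1), other filters, median-of-ratios and TPM scaling, variance without a trend, a minimum log2 fold change of 1, the replicate number as a block, separate fits, array weights for the difference between times, and the omission of each library in turn. Chosen after seeing the data were array weights for the other results, a lowess correction for gene length, protein-coding genes only, a term for sex in brain, estimated from expression because the labels give none, and combined settings without CT-179 144 h replicate 2 or brain vehicle replicate 2. Calculations outside R used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots used matplotlib 3.10.9.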

Results

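Transcript levels were measured by RNA sequencing in PTCP53 304 cells, a mouse SHH medulloblastoma line, after 24 h or 144 h of vehicle or CT-179, and in whole brains of Ptch1+/- mice dosed from postnatal day 3 to postnatal day 15. Each of the 6 groups held 3 libraries. The implied depth of the cell libraries was 4.09e+07, 4.27e+07 and 2.86e+07 reads for vehicle at 24 h, 6.87e+07, 4.00e+07 and 4.78e+07 for CT-179 at 24 h, 4.57e+07, 3.99e+07 and 4.10e+07 for vehicle at 144 h, and 4.19e+07, 5.28e+07 and 4.60e+07 for CT-179 at 144 h. In brain it was 4.67e+07, 1.70e+07 and 4.98e+07 for vehicle and 5.06e+07, 6.09e+07 and 4.60e+07 for CT-179. At 144 h, CT-179 replicate 2 stood apart, with correlations of 0.941 and 0.943 to its own group, where the other cell libraries correlated at 0.996 or more within their groups. Brain vehicle replicate 2 had 12.99% of its implied reads in Lars2 and the overlapping gene Gm15564, against 0.07% to 0.08% in the other brain libraries.

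Olig2, the transcript of the drug's target (ENSMUSG00000039830.9, mm10 chromosome 16, 91225457 to 91228677) stood at 401 ± 10.9 FPKM with CT-179 and 382 ± 15.2 FPKM with vehicle at 24 h (SD, n = 3 each, exact permutation p = 0.2). At 144 h it stood at 203 ± 19.7 and 201 ± 4.27 FPKM (SD, n = 3 each, exact permutation p = 1). In brain it stood at 27.7 ± 1.52 FPKM in the libraries labelled CT-179 and 24.6 ± 1.99 FPKM in those labelled vehicle (SD, n = 3 each, exact permutation p = 0.2). The smallest p that this test allows is 0.1, so it could not pass 0.05. Its limma adjusted p was 1, 0.95 and 0.97 for log2 fold changes of 0.07, 0.01 and 0.16. Without CT-179 144 h replicate 2 and with median-of-ratios scaling it passed at 24 h (0.11, adjusted p = 0.023) and at 144 h (0.12, adjusted p = 0.02), and with array weights at 144 h (0.08, adjusted p = 0.023). At 144 h its sign turned with TPM scaling (-0.19), the length correction (-0.13) and the omission of vehicle replicate 3 (-0.01), CT-179 replicate 1 (-0.04) or CT-179 replicate 3 (-0.03). An inhibitor of the protein need not alter its transcript, so these levels do not check the treatment labels.

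The comparison at 24 h asked what CT-179 does to the cells early. Malat1, a nuclear long noncoding RNA (ENSMUSG00000092341.3, chromosome 19, 5795690 to 5802672), fell from 21.9 ± 1.40 FPKM with vehicle to 9.59 ± 0.786 FPKM with CT-179 (SD, n = 3 each), a log2 fold change of -1.11 (SE 0.16, limma adjusted p = 0.033). Wsb1, which encodes a substrate receptor of a ubiquitin ligase, fell from 18.0 ± 0.903 to 8.91 ± 0.403 FPKM (log2 fold change -0.94, adjusted p = 0.033). Among the smaller falls, picked after the results were seen, were the kinase genes Clk1 and Clk4 (log2 fold changes -0.51 and -0.48) and the cyclin genes Ccnl1 and Ccnl2 (-0.54 and -0.42), and no list of genes that act with them was tested. Several small RNA genes fell, with -2.07 for Mir5125, -2.0 for Snord49a, -1.79 for Snord78, -1.65 for Gm23212, -1.49 for Snord80 and -1.11 for Snora3, and so did the unnamed long noncoding gene Gm3764 (-1.25). The small RNA genes lie inside Srrm2, 2410006H16Rik, Gas5 and Rpl27a, so reads of a host transcript cannot be told from their own, and the kit and column are not made for such short RNAs.

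In all, 33 genes fell and 0 rose at 24 h by limma, with 640 of 12510 genes at an unadjusted p under 0.05. Gli1, a target and effector of SHH signalling, had a log2 fold change of -0.25 (adjusted p = 0.62), and the proliferation marker Mki67 one of -0.41 (49.6 ± 1.99 against 66.3 ± 2.51 FPKM, SD, n = 3 each, adjusted p = 0.89). Olig1 and the cell cycle inhibitor Cdkn1a both had one of 0.08. The count rested on the library that stood apart at 144 h, which widens the spread shared by all groups. Without it 1007 genes rose and 1755 fell, and median-of-ratios scaling of the same 11 libraries gave 1968 and 1224. Leaving out any other cell library except CT-179 144 h replicates 1 and 3 left 1 to 8 genes.

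Without that library Gli1 and Mki67 fell (adjusted p = 0.0031 and 3.6e-04), as did 7 of 16 measured SHH pathway genes, the count of 7 being the same when adjusted over the list alone. Cdon, Gli3 and Ptch1 were among them, with log2 fold changes of -0.20, -0.18 and -0.21. Mki67 went against its list of G2/M genes, whose median was 0.06 with all libraries. Its fall therefore does not speak for proliferation genes as a group. Of 13 Notch pathway genes 4 fell and 1 rose (4 and 1 adjusted over the list alone), with -0.42 for Notch2 and -0.36 for Notch1 on the log2 scale. The matrix genes Fbn1 and Fn1 fell (-0.61 and -0.59), and so did the precursor cell proteoglycan genes Vcan and Cspg4 (-0.44 each), which belong to a list of 14 precursor markers with 4 lower and 2 higher (4 and 2 adjusted over the list alone). None of these lists passed camera, and for SHH genes the adjusted p was 0.06. Fold changes at 24 h fell with transcript length (rho -0.52), and after the correction for length Gli3 and Ptch1 no longer passed (adjusted p = 0.10 and 0.27), while Gli1 did (0.0074). With that correction 1142 genes rose and 901 fell in these 11 libraries. The values given for Mki67 and for the Notch, matrix and proteoglycan genes are without it, so part of their falls may follow length.

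Genes of cholesterol synthesis and uptake were higher as a group at 24 h. With all libraries their 25 measured members had a median log2 fold change of 0.13 (camera adjusted p = 1.3e-07, and adjusted p = 0.011 with an estimated correlation), and 0 passed singly, also when adjusted over the list alone. Without the library apart 13 rose and 0 fell, and 17 rose and 1 fell adjusted over the list alone. Msmo1, Fdps and Mvd, enzymes of the pathway, had log2 fold changes of 0.26, 0.22 and 0.27 there. The list's adjusted p with an estimated correlation was then 0.40.

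Another 4 lists passed camera at 24 h, each with 0 members past the threshold and adjusted p = 0.69 with an estimated correlation. These were lysosome and autophagy genes (24 members, median 0.07, adjusted p = 0.0015), mitochondrially encoded genes (9 members, median 0.18, adjusted p = 0.0071), cyclin-dependent kinase inhibitors and senescence genes (13 members, median 0.08, adjusted p = 0.022), and G2/M genes (26 members, median 0.06, adjusted p = 0.042, with a median of 0.00 after TPM scaling). Adjusted over each list alone the count was 0 as well. After a correction for gene length the cholesterol and lysosome lists passed and the other 3 did not, and without the library apart the G2/M list did not pass (adjusted p = 0.072).

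**Figure D1:**
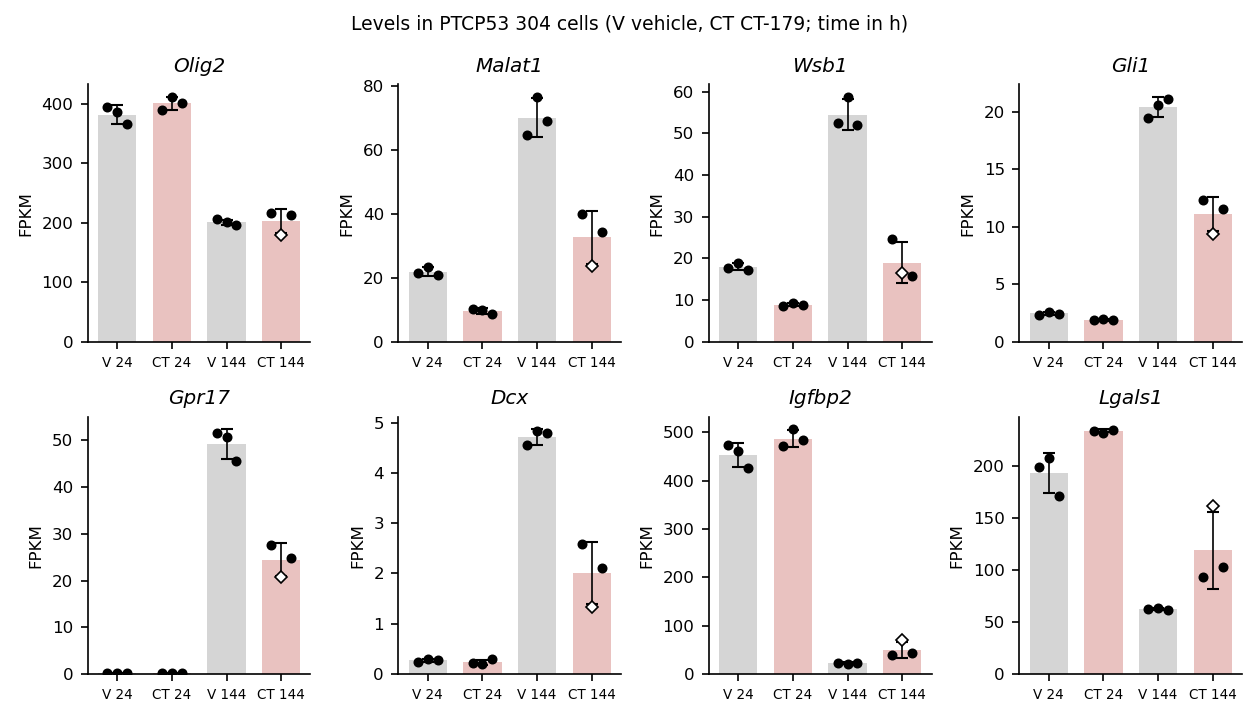
Level in FPKM (vertical axes, from 0) of 8 genes in PTCP53 304 cells with vehicle (V, grey) or CT-179 (CT, pink) at 24 h and 144 h. Bars give means, lines the SD, points the 3 libraries of a group, and white diamonds CT-179 144 h replicate 2; Gli1 stood at 11.1 ± 1.51 FPKM with CT-179 and 20.4 ± 0.890 FPKM with vehicle at 144 h, and Olig2 at 203 ± 19.7 and 201 ± 4.27 FPKM.

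At 144 h Gli1 (ENSMUSG00000025407.7, chromosome 10, 127329882 to 127341974) fell from 20.4 ± 0.890 to 11.1 ± 1.51 FPKM (SD, n = 3 each), a log2 fold change of -0.83 (SE 0.09, limma adjusted p = 0.0016). Foxm1, a transcription factor of the cell cycle, fell by 0.49 on the log2 scale, and Gas1, a cell surface partner of SHH, rose by 0.26. These were the only members past the threshold among 16 SHH pathway genes, and camera did not call the list (adjusted p = 0.14). Gpr17, a receptor of committed oligodendrocyte precursors, fell from 49.3 ± 3.16 to 24.5 ± 3.45 FPKM (log2 fold change -0.99, adjusted p = 8.4e-04), and Dcx, a marker of young neurons, from 4.72 ± 0.156 to 2.01 ± 0.626 FPKM (log2 fold change -0.95, adjusted p = 0.0033). These sizes include CT-179 144 h replicate 2, and the SD of Gli1 and Dcx was wider with CT-179 than with vehicle.

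The largest rises of named genes at 144 h were in Igfbp2, which encodes a binding protein of insulin-like growth factors (50.2 ± 16.6 against 22.7 ± 1.25 FPKM, SD, n = 3 each, log2 fold change 1.07), the iron-carrier gene Lcn2 (14.9 ± 2.40 against 6.77 ± 0.274 FPKM, 1.02), the galectin gene Lgals1 (119 ± 37.1 against 62.4 ± 1.30 FPKM, 0.88), S100a4 (0.85) and Junb (0.72). Dbx2, Htr3a and Ptgr1 rose by 0.65, 0.61 and 0.54. The long noncoding RNA Miat fell from 29.0 ± 1.26 to 7.17 ± 3.94 FPKM (log2 fold change -1.99), and Wsb1 from 54.5 ± 3.76 to 19.0 ± 4.86 FPKM (-1.50). The small RNA genes Snord49a, Mir3093, Mir3060, Mir5125, Mir6993 and Snord78 had log2 fold changes of -2.01, -1.98, -1.73, -1.71, -1.68 and -1.56, all within host genes. These rises and falls were ranked and sized with CT-179 144 h replicate 2 included. The SD of Igfbp2, Lgals1 and Miat was wider with CT-179 than with vehicle, so their sizes may rest in part on that library. Olig1 (0.35, adjusted p = 0.13), Mki67 (-0.58, adjusted p = 0.098) and Cdkn1a (0.01) did not pass, and the sign of Cdkn1a turned under TPM scaling (-0.17). Without CT-179 144 h replicate 2 Olig1 had 0.20 (adjusted p = 0.023), Mki67 -0.32 (adjusted p = 0.0017) and Cdkn1a -0.12 (adjusted p = 0.14).

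By limma 64 genes rose and 422 fell at 144 h. Without CT-179 replicate 2 of that time, 1472 rose and 2108 fell, and with median-of-ratios scaling of those 11 libraries 2170 and 1676. A separate fit of the 6 libraries of 144 h called 0 genes, with 1071 at an unadjusted p under 0.05. Leaving out a vehicle library of 144 h left 122 to 141 genes, and leaving out CT-179 replicate 1 gave 1142.

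Oligodendrocyte precursor markers were lower as a group at 144 h, with a median log2 fold change of -0.43 over 14 members (camera adjusted p = 0.033, and adjusted p = 0.51 with an estimated correlation). Gpr17 and the matrix gene Tnr (-1.12, and -0.73 without the library apart) fell and 0 rose, and 5 fell adjusted over the list alone. Pan-neuronal genes had a median of -0.19 over 15 members (adjusted p = 0.026, and adjusted p = 0.51 with an estimated correlation). Dcx and Snap91 (-0.44) fell, 2 members also when adjusted over the list alone. Without the library apart the medians were -0.20 and -0.22 and 8 members of each list fell, with adjusted p of 0.0013 and 0.0011, and adjusted p = 0.42 for both with an estimated correlation. Neural stem cell genes were higher, with a median of 0.21 over 15 members (adjusted p = 0.032, and adjusted p = 0.51 with an estimated correlation). Vim, the intermediate filament gene of progenitors, rose from 569 ± 26.6 to 776 ± 84.2 FPKM (SD, n = 3 each), and 3 members rose adjusted over the list alone. These 3 lists also passed after the correction for gene length, but the neural stem cell list did not pass without the library apart (median 0.09, adjusted p = 0.061).

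A further 6 lists passed camera at 144 h and did not after the correction for length. Hypoxia and glycolysis genes (22 members, median 0.22, adjusted p = 0.026, and adjusted p = 0.60 with an estimated correlation) and mitochondrially encoded genes (9 members, median 0.26, adjusted p = 0.033, and 0.51 with an estimated correlation) had 0 members past the threshold. So did lysosome and autophagy genes (24 members, median 0.13) and cyclin-dependent kinase inhibitors and senescence genes (13 members, median 0.10), both with adjusted p = 0.033, and adjusted p = 0.57 with an estimated correlation. In these 4 lists the count adjusted over the list alone was 0. Integrated stress and unfolded protein response genes (25 members, median 0.13, adjusted p = 0.033, and 0.51 with an estimated correlation) held 1 changed member, the cystine transporter gene Slc7a11, which fell by 0.48 on the log2 scale. Immediate early genes (11 members, median 0.16, adjusted p = 0.033, and 0.51 with an estimated correlation) held Junb, which rose. In both lists 1 member passed adjusted over the list alone. Without the library apart the medians were 0.13 for hypoxia, 0.12 for mitochondrial, 0.03 for lysosome, 0.05 for kinase inhibitor, 0.05 for stress response and 0.07 for immediate early genes. TPM scaling moved the median of all genes at 144 h by -0.19 and turned the medians of the lysosome, kinase inhibitor, stress response and immediate early lists to -0.06, -0.08, -0.03 and -0.01.

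Some lists that did not pass held changed members at 144 h. Among MAPK feedback genes Dusp6 rose by 0.31 and Fgfr3 fell by 0.36 on the log2 scale, among astrocyte markers Aldoc rose by 0.31 and the connexin gene Gja1 and Fgfr3 fell, Gja1 by 0.48, and among NRF2 and oxidative stress genes Nqo1 rose by 0.37 and Slc7a11 fell. Dusp6 stood close to the filter of 1 FPKM with vehicle at that time. Without the library apart MAPK feedback genes passed camera, with 9 of 15 higher and 2 lower (adjusted p = 0.0011, and adjusted p = 0.27 with an estimated correlation), and of the lists named above only precursor, pan-neuronal and hypoxia genes still did.

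**Figure D2:**
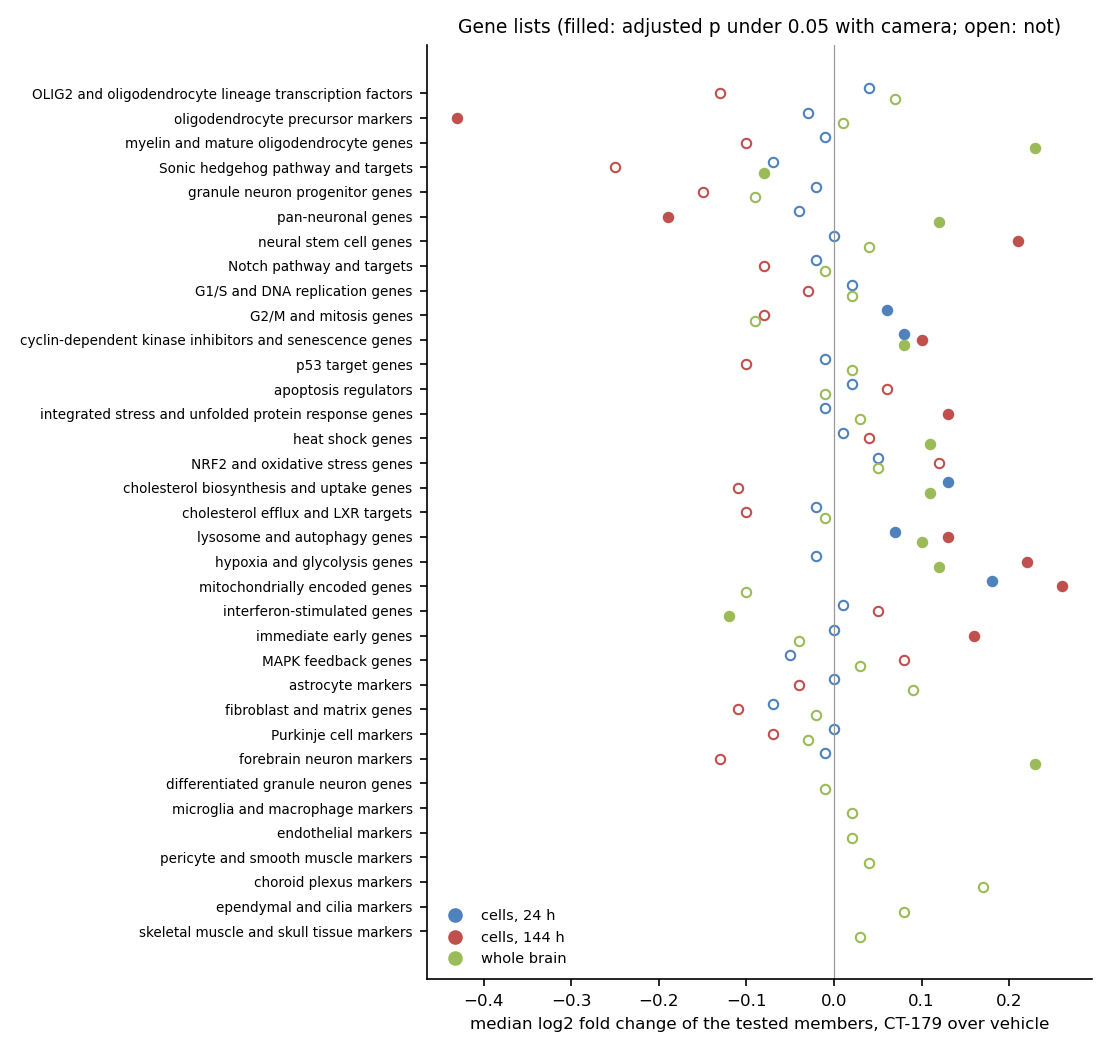
Median log2 fold change of the tested members of each gene list (horizontal axis, CT-179 over vehicle) at 24 h (blue), at 144 h (red) and in whole brain (green), with filled points for an adjusted camera p under 0.05 and open points otherwise. Oligodendrocyte precursor markers lay lowest, at -0.43 at 144 h (-0.20 without CT-179 144 h replicate 2), and myelin genes stood at 0.23 in brain.

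The fold changes followed transcript length across protein-coding genes. Spearman's rho with exonic length was -0.52 at 24 h and -0.68 at 144 h, and -0.44 at 144 h without the library apart. The shortest of 10 bins of genes had a median log2 fold change of 0.10 at 24 h and 0.37 at 144 h, and the longest -0.10 and -0.38. In vehicle, 144 h over 24 h gave a rho of 0.05. Genes are not independent replicates, so these describe the libraries.

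**Figure D3:**
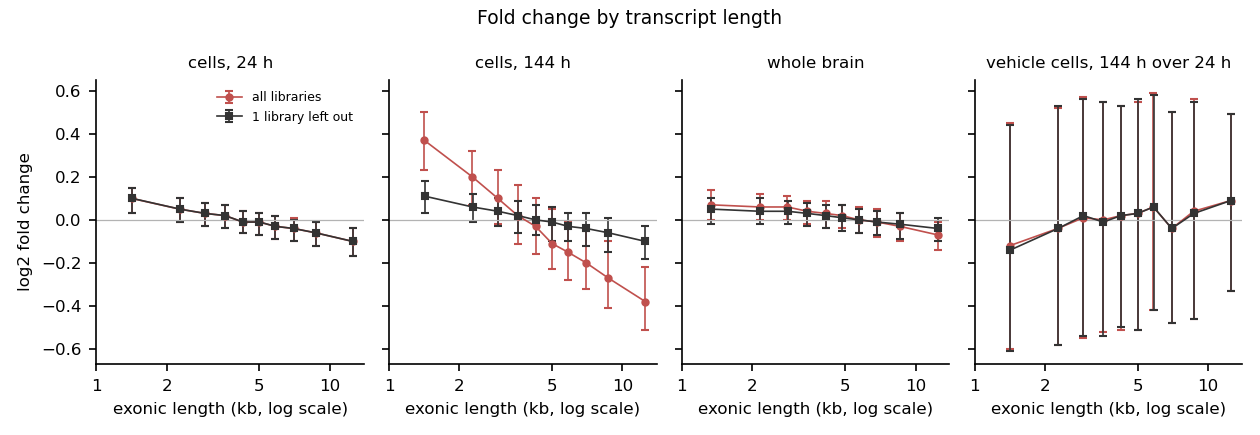
Median log2 fold change with quartile bars (vertical axis) of protein-coding genes in 10 bins of exonic length (horizontal axis, kb, log scale) for CT-179 over vehicle in cells at 24 h, at 144 h and in whole brain, and for 144 h over 24 h in vehicle cells. Red circles hold all libraries and black squares those left without CT-179 144 h replicate 2 or brain vehicle replicate 2; at 144 h the shortest and longest bins lay at 0.37 and -0.38 with all libraries and at 0.11 and -0.10 without that library.

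The effects of CT-179 at the 2 times were compared by their difference. By limma 0 genes differed, with 574 at an unadjusted p under 0.05. Without CT-179 144 h replicate 2 the difference passed for 331 genes, 149 higher and 182 lower at 144 h. Of the 33 genes that fell at 24 h, 29 also fell at 144 h and 0 rose, where independent lists would share 1.1, although both times rest on a common estimate of spread. Separate fits shared 0 genes, which was fixed in advance, as the separate fit at 144 h called 0. Without CT-179 144 h replicate 2, 497 genes were higher at both times, 1106 lower at both and 36 changed in opposite directions. The 29 genes shared with all libraries included Malat1 (-1.11 at both times), Wsb1, Clk1 (-0.51 and -0.82), Ccnl1 (-0.54 and -0.77) and Clasrp (-0.55 and -0.94). Across genes the fold changes of both times correlated with Pearson's r 0.66 and Spearman's rho 0.69.

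Time in culture changed far more genes than CT-179 did. In vehicle 4268 genes were higher and 4054 lower at 144 h than at 24 h. The replication and mitosis programme fell throughout, with 26 of 26 G1/S genes and 26 of 26 G2/M genes lower (medians -2.65 and -3.22, camera adjusted p = 2.7e-16 and 3.5e-16, and adjusted p = 4.5e-04 and 0.0077 with an estimated correlation). The mitotic kinase genes Aurkb and Plk1 fell (log2 fold changes -3.66 and -3.85), Aurkb from 54.7 ± 1.01 to 3.41 ± 0.148 FPKM (SD, n = 3 each). Of 14 astrocyte markers 13 rose and 1 fell (median 2.20, adjusted p = 1.8e-05, and adjusted p = 0.020 with an estimated correlation). Dusp6, a MAPK phosphatase induced by the pathway it restrains, fell from 95.5 ± 2.39 to 1.19 ± 0.0600 FPKM. Mmd2, Capn1, Ttyh1, Sparcl1 and Bhlhe41 rose by 5.22, 5.50, 4.78, 4.82 and 4.55, and Sting1 and Car3 fell (-4.85 and -4.94).

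Another 7 lists passed in this contrast but not with an estimated correlation, and their counts were those adjusted over all genes. Lysosome genes rose in 22 of 24 (median 1.29, adjusted p = 0.10 with an estimated correlation), interferon-stimulated genes in 20 of 21 (1.81, also 0.10) and pan-neuronal genes in 11 of 15 (1.02, adjusted p = 0.068 with an estimated correlation). MAPK feedback genes fell in 13 of 15 (-1.76, adjusted p = 0.066 with an estimated correlation) and glycolysis and hypoxia genes in 19 of 22 (-0.97, adjusted p = 0.34 with an estimated correlation). Of 13 Notch pathway genes 8 rose and 2 fell, and of 13 heat shock genes 1 rose and 8 fell, both with adjusted p = 0.10 with an estimated correlation. Adjusted over each list alone the counts were the same, except that 2 heat shock genes rose. TPM scaling moved the median of all genes by 0.10.

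In whole brain the question was what 12 days of CT-179 do to the tissue of Ptch1+/- mice, and by limma 0 of 13422 genes passed, with 490 at an unadjusted p under 0.05. Directions follow the treatment label of each library, although the letters in the sample descriptions can be read the other way. Myelin and mature oligodendrocyte genes were higher as a group in the libraries labelled CT-179, with a median log2 fold change of 0.23 over 20 members (camera adjusted p = 3.1e-11, and adjusted p = 0.47 with an estimated correlation). Fa2h, an enzyme of myelin lipid synthesis, stood at 88.0 ± 2.16 against 70.0 ± 5.02 FPKM, and the myelin protein gene Cldn11 at 562 ± 36.1 against 448 ± 19.7 FPKM (SD, n = 3 each). Interferon-stimulated genes were lower, with a median of -0.12 over 14 members (adjusted p = 0.0011, and adjusted p = 0.62 with an estimated correlation), Ifit3 standing at 3.81 ± 0.514 against 6.15 ± 0.821 FPKM. SHH pathway genes had a median of -0.08 over 16 members (adjusted p = 0.023, and adjusted p = 0.80 with an estimated correlation), and the call was lost without vehicle replicate 2 (median -0.03, adjusted p = 0.45).

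The other lists passing in brain had higher medians. They were lysosome (0.10), cholesterol (0.11), glycolysis and hypoxia (0.12), pan-neuronal (0.12), heat shock (0.11), forebrain neuron (0.23) and cyclin-dependent kinase inhibitor genes (0.08, and 0.00 after TPM scaling). Their camera adjusted p-values were 7.6e-04, 0.0011, 0.0017, 0.0083, 0.020, 0.023 and 0.045 in that order. With an estimated correlation no brain list passed, and the lowest adjusted p was 0.47. No member of any of the 10 lists passed over all genes, and adjusted over the list alone 1 interferon-stimulated gene was lower and 1 kinase inhibitor gene higher. Without vehicle replicate 2, 13 lists passed, and the heat shock list, with a median of 0.05, did not. The groups also differed in their share of males and females, judged from expression, and with a term for sex all 10 lists passed in the same direction among 14 in total, again 0 with an estimated correlation. Brain fold changes also followed exonic length, with a rho of -0.40 with all libraries and -0.28 without vehicle replicate 2.

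Genes with small p-values in brain are given as values, each with a limma adjusted p of 0.97. The hormone gene Trh had a log2 fold change of 0.66, Cd47 0.46, Cdkn1a 0.40 (21.7 ± 2.07 against 16.2 ± 0.326 FPKM, SD, n = 3 each) and Sstr3 0.36. The imprinted noncoding RNA Meg3 had one of -0.54, Coro6 -0.47, Dnase1l2 -0.45, Paxbp1 -0.39 and Ddb2 -0.37. Olig1 had one of 0.24, Sox10 of 0.07, Gli1 of -0.23 and Mki67 of -0.15, the last 2 being -0.09 and 0.00 without vehicle replicate 2.

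The authors' deposited table lists 17 brain genes at a false discovery rate under 0.05, 11 higher and 6 lower in the libraries labelled vehicle. The authors' deposited table gives a log2 fold change, vehicle over CT-179, of -6.09 for Tpm3-rs7, a tropomyosin-related gene, with a false discovery rate of 3.7e-107. Its levels were 0.223, 16.7 and 0.304 FPKM in the libraries labelled vehicle, with replicate 2 left out by the authors, and 21, 16.9 and 16.4 FPKM in those labelled CT-179. In the authors' deposited table Meg3 stands at 0.66, Cnpy1, a gene of the midbrain and hindbrain boundary, at 0.63 and the forebrain transcription factor gene Fezf2 at -3.98. Fezf2 was low and its groups overlapped, with 0.0414, 0.674 and 0.0635 FPKM under the vehicle label and 1.07, 1.27 and 0.191 FPKM under the CT-179 label. Several listed genes, such as Zfp125, Srp54a, Aadac, Elovl3 and Bpifa1, stayed under 1 FPKM in every brain library, so their large fold changes rest on low values. Of the 17 genes 8 lie on chromosome 12, which holds 754 of the 19464 genes of the table, and 6 of these lie between 18773494 and 21554521. Pseudogenes make up 7 of the 17, among them, with the values of the authors' deposited table, Zfp125 (3.55) and Gm10478 (5.22), which may share reads with related copies.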

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

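The gene test of the difference between times and the search for markers of other cell types were set before their results were seen. List tests of that difference were not part of the plan set in advance. The tests of transcript length, library correlation, RNA quality, genomic span and GC content were chosen after the results were seen. So were those of chromosome, pseudogenes, the brain library left out by the authors and regrouped libraries.

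The effect of CT-179 differed between 144 h and 24 h for 9 gene lists in a test of the interaction by camera, given as the median log2 difference, 144 h minus 24 h. Cholesterol genes had -0.23 (adjusted p = 0.00046, and adjusted p = 0.088 with an estimated correlation), and hypoxia and glycolysis genes 0.21 (0.00046, and 0.52 with an estimated correlation). Pan-neuronal genes had -0.16 (0.0039, and 0.19 with an estimated correlation), neural stem cell genes 0.27 (0.005, and 0.33) and oligodendrocyte precursor markers -0.33 (0.0055, and 0.33). Integrated stress and unfolded protein response genes had 0.1 (0.0067, and 0.39 with an estimated correlation), with -0.03 after TPM scaling. MAPK feedback genes had 0.12 (0.0067, and 0.33 with an estimated correlation), G2/M genes -0.14 (0.0079, and 0.33) and immediate early genes 0.2 (0.0079, and 0.22). No list passed with an estimated correlation, and TPM scaling moved the median difference of all genes by -0.13. Without CT-179 144 h replicate 2, 10 lists passed, 1 of them with an estimated correlation. The difference was then -0.04 for precursor markers, 0.09 for neural stem cell genes, which no longer passed (adjusted p = 0.054), 0.14 for hypoxia and glycolysis genes and 0.19 for MAPK feedback genes. Stress response genes did not pass either (adjusted p = 0.082).

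CT-179 144 h replicate 2 stood apart from its partners. Reads from another cell type are argued against by marker genes, since 0 of 146 markers of other tissues reached 1 FPKM in it while staying under 1 FPKM in the other cell libraries, and the highest such marker stood at 0.822 FPKM. This covers only markers that were low in the other cell libraries, so fewer than 146 could count. Of 15 fibroblast and matrix genes, 11 reached 1 FPKM in at least 3 cell libraries, so that tissue was little tested. The mean correlation of this library was 0.942 with its own group, against 0.808 and 0.826 with vehicle and CT-179 at 24 h. These values argue against a swap with a 24 h group. With vehicle at 144 h the mean was 0.927, and both 144 h values lie below the 0.996 or more within the other groups. The correlations therefore cannot decide on a swap between the groups of 144 h. The difference of this library from its partners fell with exonic length at a rho of -0.69, against -0.29 to 0.19 in the other cell libraries. Its medians were 0.81 in the shortest and -0.78 in the longest of 10 bins of genes. A loss of long transcripts in this library, such as degraded RNA gives, may therefore explain it, and a true difference of that culture remains open and untested.

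Fold changes fell with transcript length in all 3 comparisons of CT-179 with vehicle. GC content is argued against, as rho with length stayed at -0.36 or lower after a correction for it. An effect on transcription elongation could follow the length of the gene on the chromosome. With exonic length held, that length had a rho of 0.03 at 24 h and in brain, which argues against it there. At 144 h the rho was 0.01 without the library apart, which argues against it for the remaining libraries. With that library included the rho was -0.17, which keeps it open there. A difference in RNA quality between groups may contribute, since the fold changes at 24 h and in brain followed the profile of the library apart at a rho of 0.55 and 0.45, and of 0.38 and 0.28 after length was removed. The brain values may rest in part on 1 library. Without brain CT-179 replicate 1, Spearman's rho of the brain with the 144 h fold changes went from 0.53 to 0.13. Nor do these values separate RNA quality from a true difference of the culture that stood apart. An effect of CT-179 on long transcripts is confounded with the groups and remains open.

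The 17 brain genes of the authors' deposited table may reflect differences between mice other than the treatment. A background or strain variant could give their crowding on chromosome 12, but that chromosome was picked because of the crowding and some of the genes overlap, so the Fisher's exact p of 8.7e-08 does not test it. Reads shared between related copies could contribute, and 7 of the genes are pseudogenes, against 8.8% of the table (Fisher's exact p = 3.7e-04, and 0.0076 with overlapping genes counted as 1 locus). Pseudogenes were also picked after the genes were seen. All 6 called genes between 18773494 and 21554521 on chromosome 12 are pseudogenes, so these p-values largely restate the crowding and do not test shared reads. Vehicle replicate 2, which the authors' comparison left out, lay nearer the libraries labelled CT-179 for 11 of the 17 genes, among them Tpm3-rs7, and nearer vehicle for 6, among them Cnpy1 and Meg3. An effect of CT-179 cannot be told apart from these by that count, since it rests on 1 library.

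The 6 libraries of a comparison allow 10 splits, too few for a share under 0.05. The real split called 33 genes at 24 h, 486 at 144 h and 8322 for time in vehicle, each with 0 as the highest of the other splits, so 1 of 10 splits was as large in each. For lists at 24 h the real split gave 5 and the highest other 5, with 2 of 10 as large, and at 144 h 9 and 8, with 1 of 10 as large. In brain 10 lists passed in the real split and 13 in the highest other, with 4 of 10 as large. For genes in brain (real 0, highest other 8) and genes differing between times (real 0, highest other 1), 10 of 10 and 100 of 100 splits were as large, which a real count of 0 fixes in advance, so these counts say nothing about chance.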

How the results depend on the processing

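Array weights (except for the difference between times), the correction for gene length, protein-coding genes only, the term for sex and the combined settings of 11 cell or 5 brain libraries were chosen after the data were seen. Named genes kept their direction and side of the threshold in 1479 of 1818 values at 144 h, 625 of 825 at 24 h, 1070 of 1078 in brain and 270 of 270 for time in vehicle. The cause of the changes listed here was not tested. The estimation of array weights stopped before it converged in at least 1 fit, so values with array weights are approximate. Count-based alternatives were not run because the values are FPKM. With 0 genes called in brain, the term for sex also gave 0, and 14 lists.

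The count of 33 genes at 24 h became 11 with FPKM of at least 5, 19 with median-of-ratios scaling, 13 with TPM scaling, 10 with a log2 fold change of at least 1, 4 with protein-coding genes only, 3319 with array weights and 1996 in a separate fit. For 11 cell libraries it was 3192 with median-of-ratios scaling and 2043 with the length correction. The 486 genes at 144 h became 200 with FPKM of at least 5, 60 with a log2 fold change of at least 1, 5990 with array weights and 0 in a separate fit, and for 11 libraries 3846 with median-of-ratios scaling and 2946 with the length correction. The 0 genes differing between times became 28 without the filter, 1 each with FPKM of at least 5, TPM scaling and protein-coding genes only, 8 with the length correction and 1231 with array weights, and for 11 libraries 320 with median-of-ratios scaling and 386 with the length correction. Time in vehicle gave 2847 with a log2 fold change of at least 1. For 5 brain libraries median-of-ratios scaling and the length correction each gave 1 gene.

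The replicate number as a block left 2 genes at 24 h, 301 at 144 h and 2 shared between them. For 11 libraries the block gave 2561, 3089 and 150 for the difference, and for 5 brain libraries 25. Same-numbered libraries did not deviate together, with correlations of -0.01 to 0.06 at 24 h, -0.13 to -0.02 at 144 h, -0.01 to 0.03 for time and -0.39 to 0.11 in brain. In that order 2, 0, 2 and 1 of 6 libraries correlated best with their own number, so no pairing by number was seen. At 144 h CT-179 replicate 2 dominates the deviations of its group, which could hide a pairing.

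Passing lists at 24 h fell from 5 to 2 with the length correction, and for 11 libraries from 4 to 2. With all libraries 1 passed with an estimated correlation and 1 with fry, and with 11 libraries 0 and 10. At 144 h the length correction took 9 lists to 3, and for 11 libraries 4 to 3. With all libraries 0 passed with an estimated correlation and 3 with fry, and with 11 libraries 0 and 12. In brain 10 became 0 with an estimated correlation and 0 with fry. The 29 genes shared by 24 h and 144 h became 8 with a log2 fold change of at least 1. They became 11 with FPKM of at least 5, 17 with median-of-ratios scaling, 12 with TPM scaling and 3 with protein-coding genes only. Separate fits shared 0, as the one at 144 h called 0. With array weights 771 higher and 1558 lower genes were shared, and for 11 libraries 1092 and 784 with median-of-ratios scaling and 562 and 545 with the length correction.

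Leaving out each library gave 1 to 2762 genes at 24 h, 122 to 3580 at 144 h, 0 to 331 for the difference, 7456 to 10922 for time, 0 to 1 in brain and 1 to 1603 shared, and 4 to 5, 4 to 10 and 7 to 13 lists at 24 h, 144 h and in brain. The 24 h count moved by over 1.5 times without any cell library but CT-179 144 h replicates 1 and 3. The 144 h count did so without any but vehicle 24 h replicate 3 (343) and CT-179 144 h replicate 3 (349). The shared count did so without any but CT-179 144 h replicate 1. The count of differences moved without CT-179 144 h replicate 1 (3) and 2 (331), the lists at 144 h without replicate 2 (4), and the brain count without vehicle replicate 2 or CT-179 replicate 2 (1 each, Tpm3-rs7 in the former case).

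Olig2 had log2 fold changes of 0.04 to 0.09 at 24 h, -0.04 to 0.09 at 144 h and 0.13 to 0.23 in brain when each library was left out, the reversed values at 144 h being -0.01, -0.04 and -0.03. It was 0.11 at 24 h for 11 libraries with median-of-ratios scaling (limma adjusted p = 0.023), and at 144 h -0.19 with TPM scaling, -0.13 with the length correction, 0.08 with array weights (adjusted p = 0.023) and 0.12 for 11 libraries with median-of-ratios scaling (adjusted p = 0.02). Cdkn1a at 144 h reversed to -0.17 with TPM scaling, -0.01 without vehicle 144 h replicate 2, -0.12 without CT-179 144 h replicate 2, -0.02 with the length correction and -0.08 with array weights, and for 11 libraries to -0.10 with median-of-ratios scaling, -0.13 with the replicate block and -0.13 with the length correction. With the length correction at 144 h Dlg4 reversed to 0.16, Cdkn2b to -0.03, mt-Cytb to -0.03 and mt-Nd2 to -0.02, and with TPM scaling Igfbp3 to 0.00. In brain Sox10 reversed to -0.03 with TPM scaling. Mki67 in brain ranged from -0.48 to 0.02 when each library was left out, reversing to 0.02 without vehicle replicate 3 and without CT-179 replicate 2, to 0.01 with array weights and, for 5 libraries, 0.17 with the replicate block and 0.03 with the length correction. With array weights Bcl11b reversed to -0.01 and Camk2a to -0.18.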

Other observations

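The values in this part were looked at only after the results above were seen, and no explanation of them was tested.

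Small RNA genes had medians below 0 with CT-179 at both times, and no test of these classes was run. The 126 snoRNA genes tested had a median log2 fold change of -0.65 at 24 h, with 6 lower and 0 higher past the threshold, and of -0.70 at 144 h, with 22 lower and 0 higher. The 74 miRNA genes had medians of -0.37 and -0.49, with 1 and 13 lower. Of the 200 snoRNA and miRNA genes, 180 lie inside another annotated gene, as do 7 of the 7 called at 24 h and 34 of the 35 called at 144 h. The hosts include Gas5, Eif4a1, Srrm2 and genes of ribosomal proteins. Processed pseudogenes had medians of 0.11 and 0.19, and protein-coding genes of -0.01 and -0.05.

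The 29 genes that fell at both times in cells also had mostly lower values in the brain libraries labelled CT-179, where 23 of them were tested. Of these 22 had a log2 fold change below 0 and 1 above it (Cd68, 0.11), with a median of -0.32, while 44% of all brain genes lay below 0. The unadjusted limma p was under 0.05 for 16 of the 23, and none passed after adjustment over all genes. Malat1 stood at 50.6 ± 15.8 FPKM in the brains labelled CT-179 and 126 ± 60.2 FPKM in those labelled vehicle (SD, n = 3 each), where vehicle replicate 2 held the highest value, 195 FPKM. Clk1 stood at 11.9 ± 1.64 and 17.3 ± 1.31 FPKM, and Ccnl2 at 26.0 ± 2.63 and 34.3 ± 1.23 FPKM. Across the 11152 genes tested in cells and brain, the brain fold changes correlated with those at 24 h at Pearson's r 0.42 and Spearman's rho 0.49, and at 0.34 and 0.37 after the correction for gene length. Without brain CT-179 replicate 1 the correlation with 24 h dropped to Pearson's r 0.27 and Spearman's rho 0.26, and Pearson's r with 144 h from 0.45 to 0.13. Genes are not independent replicates, and the direction in brain depends on the treatment label.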
